A study of Mus musculus with 21 samples.

How the data were processed

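RNA was sequenced from the lungs of female A/J mice at 22 weeks, per the labels. The mice had received NNK, a nicotine-derived tobacco carcinogen, as 1 intraperitoneal dose of 100 mg/kg, or its vehicle. Some groups then received LPS, a bacterial cell wall product, at 5 µg per mouse in 50 µL by the intranasal route 1 time per week, starting 1 week after NNK. Silibinin (Sil) and indole-3-carbinol (I3C), both chemopreventive agents, were given in the diet at 20 µmol/g each. The 7 groups of 3 libraries were Control, NNK, LPS, NNK_LPS (NNK then LPS), and NNK_LPS with Sil, with I3C, or with both (Sil_I3C). Per the labels' protocols, the RNA of the NNK groups came from dissected lung tumours, pooled from 3 mice per group, and that of the Control and LPS groups came from normal lung, so tumour tissue and NNK treatment cannot be separated. The labels do not say whether the 3 libraries of a group came from separate mice or from 1 pool. Within NNK, Zbtb16 stood at 269, 305 and 8.35 CPM, and within LPS, Dlk1 stood at 23.6, 0.205 and 0 CPM, differences that aliquots of 1 RNA pool do not give, so the libraries of these groups differed in their material. These genes were chosen after their values were seen. Whether each library came from 1 mouse is not given, so the p-values refer to the spread between libraries and not to a known number of mice.

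The deposited table held whole-number counts per gene symbol for the 21 libraries, with 38924 symbols, of which 16756 had 0 counts in every library. The labels' protocols name the TruSeq RNA kit, version 2. The submitters' processing notes name the mm10 build. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Values of genes with close paralogs or overlapping neighbours, such as the H2 family, Rpl23a and the immunoglobulin segments, carry that uncertainty. Total counts ran from 13.3 to 25.3 M per library.

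The counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by the trimmed mean of M-values. Genes passed filterByExpr with a minimum count of 10, which left 15770 genes for testing. A quasi-likelihood model with robust options was fitted to the 7 groups, with 14 residual degrees of freedom and a common biological coefficient of variation of 0.168. For each of 11 contrasts, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error, for 3 libraries in each compared group. Levels are CPM, counts scaled by the normalised library size, as mean ± SD with n = 3. Where a group had no counts of a gene, the fold was computed against a floor of 3 counts over the group. Where a group had 1 to 3 counts in a comparison of 2 groups in the report, the ratio of pooled counts is given with its 95% counting interval. Floors and such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

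The contrasts, the 43 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with fry from limma 3.58.1 on log2 CPM with a prior count of 2, adjusted over the lists within each contrast. Fry asks whether the genes of a list move, on balance, one way, and does not compare a list with other genes. Camera with an estimated correlation was the alternative. It asks another question, whether the genes of a list move more than the other genes. The adjusted p marked as with an estimated correlation is that of camera and not of fry. A difference between the 2 values is therefore not due to the correlation alone. Over all 11 contrasts fry called 114 list results and camera 8, which were the lists of AhR targets and NRF2 targets in 4 contrasts. Named genes were the 8 with the highest and the 8 with the lowest log2 fold change among called genes with no overlap between the groups and a mean of at least 1 CPM. Uncharacterised models and immunoglobulin or T-cell receptor segments were left out, and the overlap condition was dropped for contrasts of more than 2 groups. For each called list, up to 4 members with the smallest adjusted p were added. Genes named outside this rule are marked as chosen after their values were seen.

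The alternatives were size factors by relative log expression, no filter on low counts, DESeq2 1.42.0, a fit to the compared groups alone, the replicate number as a block, and leaving out each library. Added after seeing the data were thinning to the shallowest library, a covariate from heart muscle markers, a covariate from clock genes, leaving out 2 libraries that stood apart, a term for library batch, and a fit to the libraries of 1 batch. Counts of called genes were also compared with other splits of the libraries. The 3 library batches were not given in the labels. They were read from the ratio of mt-Atp8 to mt-Atp6 counts and from the numbers at the start of the sample titles. Coordinates came from a GRCm38 annotation, in which 91.3% of the table's symbols were found.

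The pipeline was tested on simulated data in which 100 genes were changed 2-fold and 100 genes 4-fold. For LPS versus Control it recovered 67% and 89% of them, for NNK_LPS versus NNK 75% and 90%, for Sil versus NNK_LPS 62% and 90%, and for I3C versus NNK_LPS 75% and 88%. False calls numbered 9 of 165, 10 of 175, 5 of 157 and 8 of 171. The simulated counts were independent negative binomial draws, a single draw per contrast, with no batches or other structure shared between libraries. All other genes had the same mean in all groups. These rates therefore do not give the power or error rate of the real comparisons. No library was left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.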

Results

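Gene expression was measured by RNA sequencing in 21 libraries from mouse lung, 3 in each of 7 groups. Total counts were 13.3 to 15.6 M per library in Control, 14.6 to 15.0 M in NNK, 14.7 to 15.7 M in LPS and 15.7 to 17.5 M in NNK_LPS. In the groups given dietary agents they were 16.2 to 17.2 M with Sil, 15.9 to 24.7 M with I3C and 21.4 to 25.3 M with Sil_I3C. The first and second principal components held 42.1% and 15.6% of the variance.

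**Figure D1:**
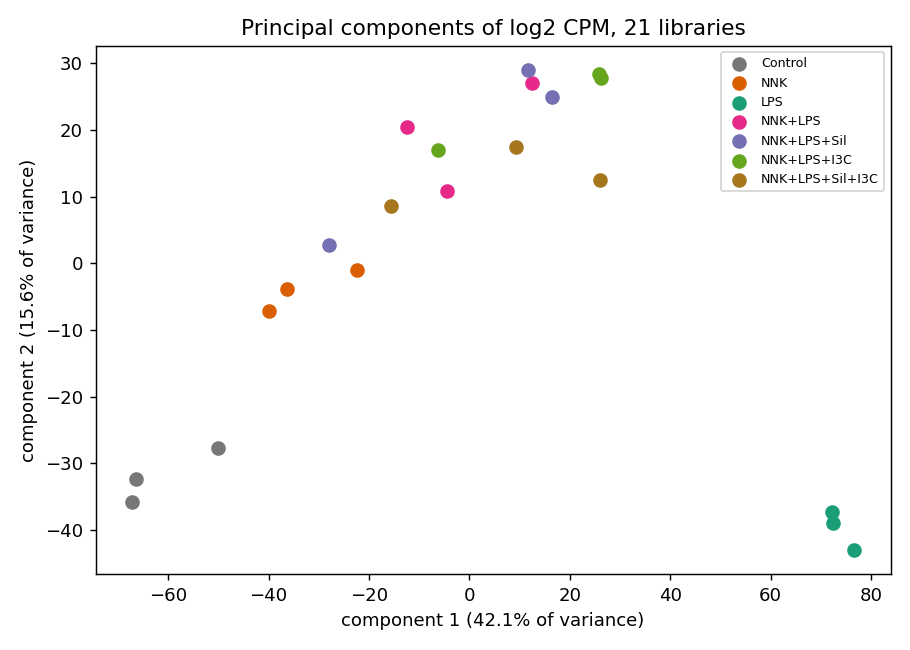
Each point is 1 of the 21 libraries, coloured by group, at its first (42.1% of variance) and second (15.6% of variance) principal component of log2 CPM. The 3 LPS libraries lie apart from the other 18 along the first component, and the 3 Control libraries lie apart from the tumour libraries.

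The libraries fell into 3 batches by the ratio of counts of mt-Atp8 to counts of mt-Atp6, adjacent genes of the mitochondrial genome. The ratio was 0.0206 to 0.0236 in libraries 1 to 8 of the title order (Control, NNK, LPS 1 and LPS 2), here batch A. It was 0.0782 to 0.0876 in libraries 9 to 16 (LPS 3, NNK_LPS, Sil and I3C 1), batch B, and 0.117 to 0.135 in libraries 17 to 21 (I3C 2, I3C 3 and Sil_I3C), batch C. NNK versus Control and Sil versus NNK_LPS therefore lay within 1 batch. NNK_LPS shared no batch with Control, with NNK or with Sil_I3C, so no within-batch value exists for these comparisons. A batch term could be fitted only because LPS and I3C spanned batches, and it rests on LPS 3 against LPS 1 and 2 and on I3C 1 against I3C 2 and 3.

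**Figure D2:**
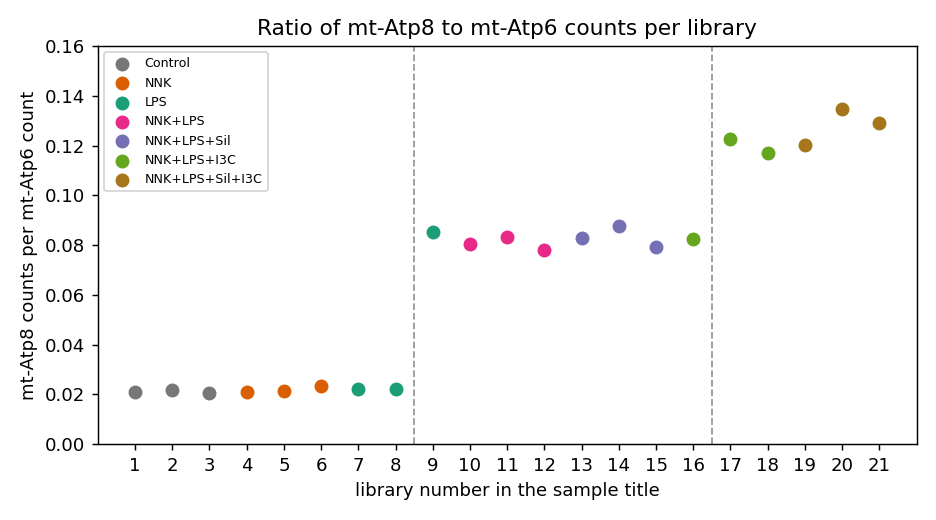
Each point is 1 library, at its number in the sample title and its ratio of mt-Atp8 to mt-Atp6 counts, coloured by group. Libraries 1 to 8 lie between 0.0206 and 0.0236, libraries 9 to 16 between 0.0782 and 0.0876, and libraries 17 to 21 between 0.117 and 0.135, and the LPS and I3C groups each have points at more than 1 level.

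The comparison of NNK tumours with Control lung asked how tumours differ from normal lung. Targets and feedback genes of RAS-MAPK signalling rose in the tumours. Etv4, a transcription factor downstream of ERK located at chromosome 11, 101769742 to 101785371 (GRCm38), rose by 3.75 ± 0.42 on the log2 scale, from 0.447 ± 0.0658 to 6.15 ± 2.93 CPM. Ereg, an EGF receptor ligand, rose by 4.55 ± 0.83, and the MAPK phosphatase gene Dusp4 by 1.45 ± 0.28. The rise of Ereg was not specific to tumours. Its summed counts were 13 in Control, 318 in NNK and 346 in LPS lung, while those of Etv4 were 20, 277 and 63. Of the 16 members of this list 10 rose and none fell, and 13 rose when adjusted over the list alone (fry adjusted p = 0.000193, adjusted p = 0.104 with an estimated correlation). Among p53 targets, 4 of 12 rose and none fell, and 6 rose when adjusted over the list alone (fry adjusted p = 0.000193, adjusted p = 0.104 with an estimated correlation). These included Zmat3 (0.86 ± 0.12) and Sesn2 (1.18 ± 0.20). Of 17 alveolar type 2 cell markers 10 rose, 11 when adjusted over the list alone (fry adjusted p = 0.00496, adjusted p = 0.363 with an estimated correlation). The surfactant gene Sftpb rose from 4144 ± 330.1 to 7042 ± 539.6 CPM, a log2 change of 0.76 ± 0.13. The MHC class II genes rose in 6 of 10 cases, 8 when adjusted over the list alone (fry adjusted p = 0.0217, adjusted p = 0.402 with an estimated correlation), among them Cd74 (1.17 ± 0.19).

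Neutrophil genes also rose in the NNK tumours, 9 of 13, and 10 when adjusted over the list alone (fry adjusted p = 0.0225, adjusted p = 0.388 with an estimated correlation). The receptor genes Csf3r and Cxcr1 rose by 1.94 ± 0.48 and 1.97 ± 0.47. Cxcr1 did not follow Csf3r in other groups, so its rise is weak evidence of neutrophils here. Summed counts in Control and LPS were 146 and 160 for Cxcr1, and 716 and 8581 for Csf3r. Those in NNK and NNK_LPS were 581 and 1017 for Cxcr1, and 2729 and 1406 for Csf3r. Club cell markers fell in 6 of 10 cases, 7 when adjusted over the list alone (fry adjusted p = 0.00496, adjusted p = 0.363 with an estimated correlation). The secretoglobin gene Scgb1a1 changed by -0.74 ± 0.19 and the carbonyl reductase gene Cbr2 by -0.58 ± 0.13. Fibroblast markers fell in 8 of 16 cases and rose in 1, and 12 fell and 1 rose when adjusted over the list alone (fry adjusted p = 0.00239, adjusted p = 0.363 with an estimated correlation). Heart muscle markers fell in 8 of 9 cases, all 9 when adjusted over the list alone (fry adjusted p = 0.00880, adjusted p = 0.363 with an estimated correlation), among them the troponin gene Tnni3 (-1.95 ± 0.45). Skeletal muscle markers fell in 2 of 6 cases by either adjustment, over all genes or adjusted over the list alone (fry adjusted p = 0.0217, adjusted p = 0.388 with an estimated correlation). Xenobiotic-metabolising enzyme genes fell in 5 of 15 cases by either adjustment (fry adjusted p = 0.00880, adjusted p = 0.363 with an estimated correlation), including Cyp2e1 (-1.88 ± 0.40). Cyp2e1 had 416 summed counts in Control and 113 in NNK. The adipocyte genes Adipoq (383 and 110) and Plin1 (264 and 114) moved the same way, and fat tissue in the pieces was not tested. AhR targets fell in 3 of 7 cases by either adjustment (fry adjusted p = 0.00896, adjusted p = 0.363 with an estimated correlation), among them Cyp1a1 (-3.90 ± 0.94), which stood at 14.2 ± 11.5 CPM in Control, with 1 Control library at 0.904 CPM. Of the 8 genes on the checkpoint list only Tgfb1, a cytokine gene, rose (0.51 ± 0.12, fry adjusted p = 0.0204, adjusted p = 0.363 with an estimated correlation). The imprinted non-coding RNA Meg3 rose by 4.30 ± 0.87, from 12.1 ± 2.20 to 239 ± 110.4 CPM, and its neighbour Rian by 3.63 ± 0.76. Npy2r, a neuropeptide Y receptor gene, had 1 count in Control and 207 in NNK, a ratio of 205 (95% interval 36.4 to 8130). Cell cycle genes fell in 3 of 30 cases by either adjustment, and the list was not called (fry adjusted p = 0.231).

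In total edgeR called 2064 of 15770 genes between NNK and Control, 1019 higher and 1045 lower in the tumours, and 312 of them changed at least 2-fold. The balance depended on the fit, with 1159 higher and 848 lower with size factors by relative log expression, 1524 and 1124 with DESeq2, and 898 and 637 without the filter on low counts. Both groups lie in batch A. Without Control 1, Control 2, NNK 1 or NNK 3 the count was 874, 502, 490 (313 higher and 177 lower) or 1058 (675 and 383), and with the mean of the heart muscle markers as a covariate it was 78. That covariate, centred, stood at 1.54 to 1.84 in Control and -0.87 to 0.47 in NNK. With no overlap between the groups, the fit cannot tell heart muscle from group. Fry called 12 lists, and 2 with the 2 groups alone in the fit.

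Repeated LPS in lung gave the highest count of called genes among the 11 contrasts, 7890 of 15770. Inflammatory cytokine and chemokine genes rose in 24 of 25 cases and fell in 1, by either adjustment (fry adjusted p = 1.52e-08, adjusted p = 0.171 with an estimated correlation). Il1b, which encodes interleukin-1 beta, rose from 7.34 ± 1.95 to 452 ± 40.9 CPM, a log2 change of 5.94 ± 0.45. Cxcl9, a chemokine that attracts activated T cells, rose by 9.88 ± 1.12. Csf3, the gene of granulocyte colony-stimulating factor, had no counts in Control and was at least 190-fold higher in LPS. The chemokine gene Cxcl11, with no counts in Control, was at least 97.1-fold higher. Saa3, an acute-phase protein gene at chromosome 7, 46711998 to 46715700 (GRCm38), rose by 10.12 ± 1.08 from 1.75 ± 0.945 CPM to 1975 ± 578 CPM. The siderophore-binding protein gene Lcn2 rose by 5.53 ± 0.46, and the mucosal defence list rose in 9 of 14 cases and fell in 1, by either adjustment (fry adjusted p = 5.52e-07, adjusted p = 0.352 with an estimated correlation). All 17 genes of the NF-kB and TLR pathway rose by either adjustment (fry adjusted p = 6.49e-08, adjusted p = 0.227 with an estimated correlation), as did all 17 interferon response genes (fry adjusted p = 7.57e-07, adjusted p = 0.352 with an estimated correlation). Examples were Tlr2 (2.66 ± 0.18) and Irf7 (4.35 ± 0.43).

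Markers of several leukocyte types rose with LPS, while mast cell and eosinophil markers fell in 4 of 7 cases and rose in 1, with 5 lower and 1 higher when adjusted over the list alone (fry adjusted p = 0.00701, adjusted p = 0.507 with an estimated correlation). All 13 monocyte and interstitial macrophage markers rose by either adjustment (fry adjusted p = 1.67e-07, adjusted p = 0.328 with an estimated correlation), 12 of 13 T cell markers rose by either adjustment (fry adjusted p = 2.94e-05, adjusted p = 0.416 with an estimated correlation), and 8 of 13 neutrophil markers rose by either adjustment (fry adjusted p = 0.000719, adjusted p = 0.423 with an estimated correlation). The regulatory T cell gene Foxp3 rose by 3.94 ± 0.61. Ifng, the interferon-gamma gene, had 1 count in Control and 294 in LPS, a ratio of 300 (95% interval 53.4 to 11890). MHC class II genes rose in 9 of 10 cases by either adjustment (fry adjusted p = 2.36e-06, adjusted p = 0.416 with an estimated correlation). All 8 genes on the checkpoint list rose by either adjustment (fry adjusted p = 2.13e-07, adjusted p = 0.231 with an estimated correlation), among them Cd274 (3.97 ± 0.33). B and plasma cell markers rose in 6 of 13 cases by either adjustment (fry adjusted p = 0.0115, adjusted p = 0.530 with an estimated correlation). Igj, the immunoglobulin joining chain gene, rose from 39.0 ± 13.8 to 1610 ± 456 CPM (5.37 ± 0.64). Of 179 immunoglobulin and T-cell receptor segments tested, 131 rose. NK cell markers rose in 4 of 7 cases by either adjustment (fry adjusted p = 0.00471, adjusted p = 0.507 with an estimated correlation). Lymphoid chemokine genes rose in 6 of 8 cases by either adjustment (fry adjusted p = 0.000101, adjusted p = 0.416 with an estimated correlation).

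Markers of several resident lung cell types fell with LPS, while mucous cell markers rose in 5 of 10 cases by either adjustment (fry adjusted p = 0.0329, adjusted p = 0.590 with an estimated correlation). All 18 endothelial markers fell by either adjustment (fry adjusted p = 0.000719, adjusted p = 0.416 with an estimated correlation), among them the angiopoietin receptor gene Tek (-1.75 ± 0.31). Alveolar type 1 markers fell in 10 of 11 cases and rose in 1, by either adjustment (fry adjusted p = 0.000719, adjusted p = 0.416 with an estimated correlation). Club cell markers fell in 6 of 10 cases by either adjustment (fry adjusted p = 4.28e-05, adjusted p = 0.416 with an estimated correlation), with Cbr2 at -1.77 ± 0.14 and Cyp2f2 at -1.81 ± 0.16. Xenobiotic-metabolising enzyme genes fell in 14 of 15 cases by either adjustment (fry adjusted p = 3.14e-08, adjusted p = 0.171 with an estimated correlation). Fibroblast markers fell in 9 of 16 cases and rose in 3, by either adjustment (fry adjusted p = 1.65e-05, adjusted p = 0.416 with an estimated correlation). All 7 adipocyte markers fell by either adjustment (fry adjusted p = 0.000719, adjusted p = 0.416 with an estimated correlation). Heart muscle markers fell in 8 of 9 cases by either adjustment (fry adjusted p = 0.00159, adjusted p = 0.424 with an estimated correlation). Summed counts in Control and LPS were 383 and 11 for Adipoq, 12687 and 2324 for Myh6, and 416 and 43 for the xenobiotic gene Cyp2e1. Fat or heart tissue in the pieces was not tested. Of 13 alveolar macrophage markers 7 fell and 3 rose, and 8 fell and 3 rose when adjusted over the list alone (fry adjusted p = 0.0272, adjusted p = 0.668 with an estimated correlation). The fatty acid binding protein gene Fabp1 changed by -5.06 ± 0.45, and the integrin gene Itgax by 2.04 ± 0.22. Extracellular matrix and invasion genes rose in 8 of 16 cases and fell in 4, with 9 higher and 4 lower when adjusted over the list alone (fry adjusted p = 6.76e-06, adjusted p = 0.416 with an estimated correlation), among them Timp1, a metalloproteinase inhibitor (4.85 ± 0.26). Immediate early and heat shock genes rose in 7 of 14 cases by either adjustment (fry adjusted p = 0.000129, adjusted p = 0.416 with an estimated correlation), and glycolysis and hypoxia genes rose in 10 of 14 cases and fell in 2, by either adjustment (fry adjusted p = 0.000126, adjusted p = 0.416 with an estimated correlation).

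**Figure D3:**
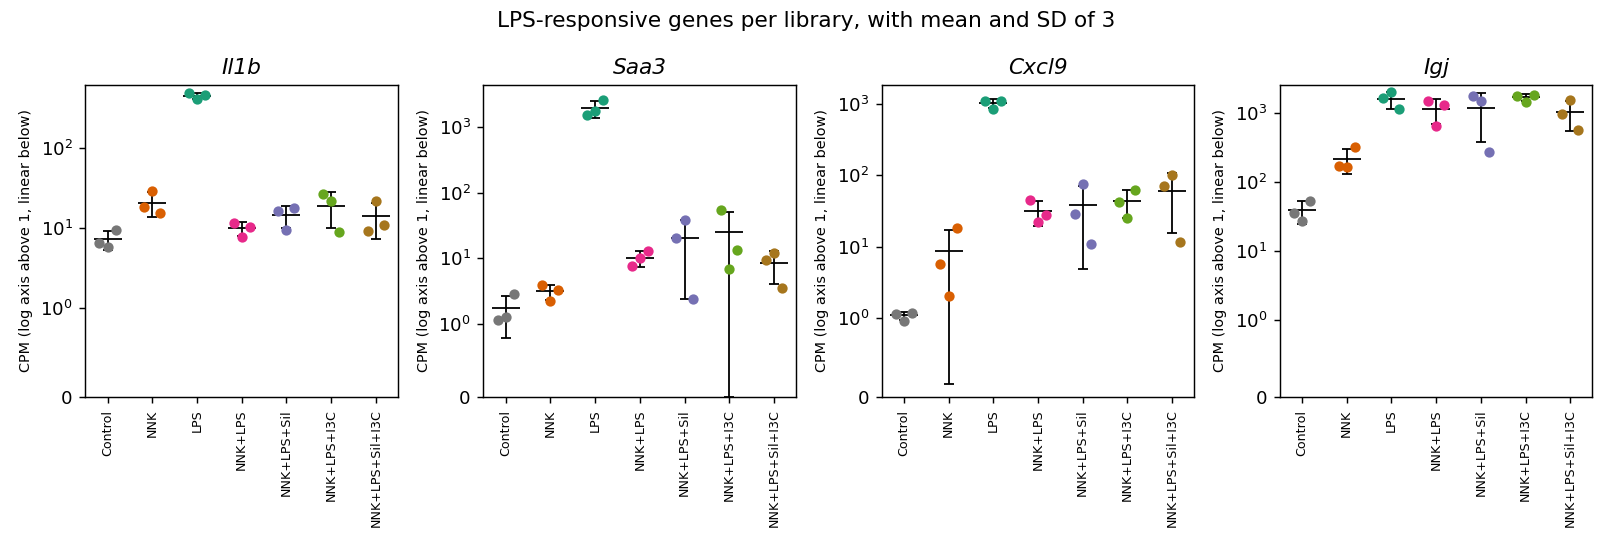
CPM of the inflammatory genes Il1b, Saa3 and Cxcl9 and the plasma cell gene Igj in the 7 groups, on an axis that is logarithmic above 1 CPM and linear below, with 1 point per library and the mean ± SD of 3 as a bar whose lower end stops at 0. Il1b averaged 452 CPM in LPS lung and 9.90 CPM in NNK_LPS tumours, while Igj averaged 1610 and 1151 CPM.

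Of the 7890 genes called between LPS and Control, 3993 were higher and 3897 lower, and 2811 changed at least 2-fold. With the batch A libraries of LPS alone 6597 genes were called, of which 6478 were among the 7890, and Il1b changed by 5.93 ± 0.48 and Cbr2 by -1.75 ± 0.16. In the same fit Ereg, Phlda1 and Dusp5 of the RAS-MAPK list rose by 4.34 ± 0.868, 0.938 ± 0.198 and 0.942 ± 0.171. Spry1 of that list changed by -1.002 ± 0.264. Of the p53 targets, Gdf15, Bax and Mdm2 rose by 1.87 ± 0.251, 0.660 ± 0.0884 and 0.605 ± 0.0791. Perp, also a p53 target, changed by -1.16 ± 0.210. Changes in members of these lists were thus not confined to tumours.

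NNK_LPS tumours were compared with Control lung to describe tumours that arose under repeated LPS. These groups share no batch. Of the 18 lists that fry called, 4 stayed called with the batch term, which were alveolar type 2 markers, p53 targets, fibroblast markers and heart muscle markers. Alveolar type 2 markers rose in 13 of 17 cases and fell in 1, with 14 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.000482, adjusted p = 0.314 with an estimated correlation). Sftpb rose by 0.97 ± 0.13 and the cathepsin gene Ctsh by 1.32 ± 0.17. RAS-MAPK feedback genes rose in 9 of 16 cases, 11 when adjusted over the list alone (fry adjusted p = 0.000120, adjusted p = 0.246 with an estimated correlation), with Etv4 at 3.77 ± 0.42. P53 targets rose in 5 of 12 cases, 9 when adjusted over the list alone (fry adjusted p = 5.75e-05, adjusted p = 0.204 with an estimated correlation). Igj rose from 39.0 ± 13.8 to 1151 ± 442 CPM (4.88 ± 0.63). T cell markers rose in 8 of 13 cases, 10 when adjusted over the list alone (fry adjusted p = 0.0151, adjusted p = 0.467 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 8 of 13 cases, 9 when adjusted over the list alone (fry adjusted p = 0.00162, adjusted p = 0.337 with an estimated correlation). MHC class II genes rose in 8 of 10 cases by either adjustment (fry adjusted p = 0.00102, adjusted p = 0.337 with an estimated correlation). Spag11b, a beta-defensin-like gene, had no counts in Control and was at least 85.9-fold higher in NNK_LPS tumours.

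Some markers of normal lung structure were lower in NNK_LPS tumours, though the endothelial and club cell lists were not called with the batch term. Endothelial markers fell in 9 of 18 cases, 12 when adjusted over the list alone (fry adjusted p = 0.0212, adjusted p = 0.543 with an estimated correlation). Fibroblast markers fell in 10 of 16 cases by either adjustment (fry adjusted p = 5.75e-05, adjusted p = 0.204 with an estimated correlation), and club cell markers in 7 of 10 by either adjustment (fry adjusted p = 0.000568, adjusted p = 0.314 with an estimated correlation). All 9 heart muscle markers fell by either adjustment (fry adjusted p = 0.000338, adjusted p = 0.314 with an estimated correlation). Glycolysis and hypoxia genes rose in 6 of 14 cases, with 7 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.0458, adjusted p = 0.564 with an estimated correlation), among them the hexokinase gene Hk2 (1.77 ± 0.34). The cytokine list was not called (fry adjusted p = 0.0576), with 4 of 25 members higher, and 2 when adjusted over the list alone. In this comparison Cxcl9 rose by 4.86 ± 1.04.

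Between NNK_LPS and Control edgeR called 3876 genes, 1886 higher and 1990 lower, and 1082 changed at least 2-fold. With the batch term 24 genes were called, 22 of them among the 3876, and 49 of the 3876 had the other sign, while Sftpb changed by 1.20 ± 0.24, Etv4 by 3.63 ± 0.80, Igj by 5.58 ± 1.19, Hk2 by 1.46 ± 0.56 and Cxcl9 by 4.67 ± 1.72, and these 5 genes were no longer called (adjusted p = 0.0548, 0.0613, 0.0613, 0.224 and 0.210). Without Control 1, Control 2, NNK_LPS 1 or NNK_LPS 2 the count was 2539, 2334, 2442 or 2294, and with the heart muscle covariate it was 352 and with the clock covariate 858. Neither covariate overlapped between NNK_LPS and Control, so these fits cannot tell covariate from group. The fold changes of NNK and of NNK_LPS against Control correlated across genes, which are not independent replicates (Pearson's r = 0.812). Groups with no change that shared the Control libraries gave a mean r of 0.505 (0.221 to 0.728). The covariance was 0.286, against 0.0419 (0.0143 to 0.0724) with no change. Both contrasts called 724 genes higher and 714 lower, against 122 and 132 for independent calls, a number that leaves out the shared Control libraries, which raise the overlap by an amount not estimated here.

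The effect of LPS in tumours was tested by comparing NNK_LPS with NNK. Ly6c2, a marker of inflammatory monocytes at chromosome 15, 75108158 to 75111970 (GRCm38), rose from 25.4 ± 2.39 to 67.6 ± 11.1 CPM, a log2 change of 1.41 ± 0.17 (adjusted p = 0.00417). Clec4a2, a C-type lectin receptor gene of myeloid cells, rose by 0.93 ± 0.17, and the tetraspanin gene Cd63 by 0.56 ± 0.10. The guidance ligand gene Slit3 fell by -1.23 ± 0.21 on the log2 scale, the organic cation transporter gene Slc22a3 changed by -1.42 ± 0.26, and the integrin gene Itga2 by -0.75 ± 0.13. The mitochondrial gene mt-Atp8 rose by 2.12 ± 0.37, Rpl23a by 1.16 ± 0.19, H2-T22 by 1.21 ± 0.22 and H2-Q1 by 1.06 ± 0.19. No list was called. The monocyte and interstitial macrophage list had 1 of 13 members higher, 8 when adjusted over the list alone (fry adjusted p = 0.375), and the fibroblast list 6 of 16 lower when adjusted over the list alone (fry adjusted p = 0.375).

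Across 14828 genes, which are not independent replicates, the log2 change between NNK_LPS and NNK fell with transcript length, the median over a gene's annotated transcripts (Spearman's rho = -0.209), with a median of 0.122 up to 600 nt and -0.229 over 8000 nt. In LPS 3 against LPS 1 and 2, a difference of batch, rho was -0.102. EdgeR called 15 genes between NNK_LPS and NNK, 10 higher and 5 lower, with 2517 at an unadjusted p under 0.05, and DESeq2 called 492. With the batch term edgeR called 0 genes, with 871 at an unadjusted p under 0.05 (DESeq2 was not run with it), and the log2 change was 1.45 ± 0.33 for Ly6c2 and 0.25 ± 0.22 for mt-Atp8, against the values above. The edgeR count was 2, 0 (1613 at an unadjusted p under 0.05) and 4 without NNK 1, NNK 2 and NNK 3, and 3, 1 and 231 without NNK_LPS 1, 2 and 3. Across genes, which are not independent replicates, the log2 change of LPS in lung correlated with that of NNK_LPS over NNK in tumours (r = 0.528, rho = 0.439, slope 0.210). These contrasts share no library, and groups with no change gave r of -0.381 to 0.370. With the batch A libraries of LPS alone r was 0.529, while the tumour groups have no batch in common. Of 1623 genes at least 2-fold higher in LPS lung, 1261 (77.7%) were higher in NNK_LPS than in NNK tumours, with medians of 2.06 in lung and 0.27 in tumours.

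The difference of these LPS effects, with and without NNK, was tested directly. Cytokine genes had a lower LPS effect in tumours in 22 of 25 cases, with 22 lower and 1 higher when adjusted over the list alone (fry adjusted p = 4.19e-06, adjusted p = 0.111 with an estimated correlation), as shown by Il1b (-7.01 ± 0.59). All 17 interferon response genes had a lower effect by either adjustment (fry adjusted p = 0.000101, adjusted p = 0.243 with an estimated correlation), as did 16 of 17 NF-kB and TLR pathway genes by either adjustment (fry adjusted p = 9.16e-06, adjusted p = 0.148 with an estimated correlation). Monocyte and interstitial macrophage markers had a lower effect in 11 of 13 cases, 12 when adjusted over the list alone (fry adjusted p = 0.000130, adjusted p = 0.243 with an estimated correlation), and neutrophil markers in 10 of 13, 11 when adjusted over the list alone (fry adjusted p = 0.00134, adjusted p = 0.363 with an estimated correlation). Xenobiotic-metabolising enzyme genes had a higher effect in 11 of 15 cases, 12 when adjusted over the list alone (fry adjusted p = 4.95e-06, adjusted p = 0.111 with an estimated correlation). Of 179 immunoglobulin and T-cell receptor segments, 15 differed. EdgeR called 3955 genes in this difference, 1690 higher and 2265 lower. With the batch term it called 3005, of which 2778 were among the 3955, and with the clock covariate 2458. The tissue differed between the compared effects, since the Control and LPS groups were normal lung and the NNK groups were tumours, per the labels.

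Dietary silibinin was compared with NNK_LPS alone within batch B, and no gene passed the threshold with edgeR or with DESeq2. At an unadjusted p under 0.05 edgeR found 578 genes. Leaving out 1 library moved this number from 372 (without NNK_LPS 2) to 1239 (without Sil 3). The AhR target genes Cyp1a1 and Nqo1 differed by 0.45 ± 1.02 and -0.12 ± 0.25, Il1b by 0.55 ± 0.40 and Sftpb by -0.12 ± 0.13. No list was called. Mucous cell markers came closest, with 4 of 10 higher when adjusted over the list alone and none over all genes (fry adjusted p = 0.435). A p that misses the threshold does not show that silibinin had no effect.

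Indole-3-carbinol raised genes of the aryl hydrocarbon receptor (AhR) pathway. Cyp1a1, a cytochrome P450 induced by AhR ligands and located at chromosome 9, 57687928 to 57703824 (GRCm38), rose from 1.58 ± 1.76 to 139 ± 63.6 CPM, a log2 change of 6.50 ± 0.86 (adjusted p = 0.00224). Nqo1, a quinone reductase gene at chromosome 8, 107388225 to 107403206 (GRCm38), rose by 2.52 ± 0.24, and the aldehyde dehydrogenase gene Aldh3a1 by 2.03 ± 0.19. Of 7 AhR targets 5 rose by either adjustment, and the call held with an estimated correlation (fry adjusted p = 1.88e-08, adjusted p = 0.000884 with an estimated correlation). NRF2 targets rose in 10 of 15 cases, with 11 higher and 1 lower when adjusted over the list alone (fry adjusted p = 3.74e-06, adjusted p = 0.0124 with an estimated correlation), among them the glutathione peroxidase gene Gpx2 (1.58 ± 0.19) and the glutathione transferase gene Gstm1 (0.94 ± 0.14). Nqo1 belongs to both lists. The carboxylesterase gene Ces1g rose by 3.25 ± 0.35. Spag11b fell from 5.81 ± 1.68 to 0.633 ± 0.451 CPM (-3.12 ± 0.59).

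**Figure D4:**
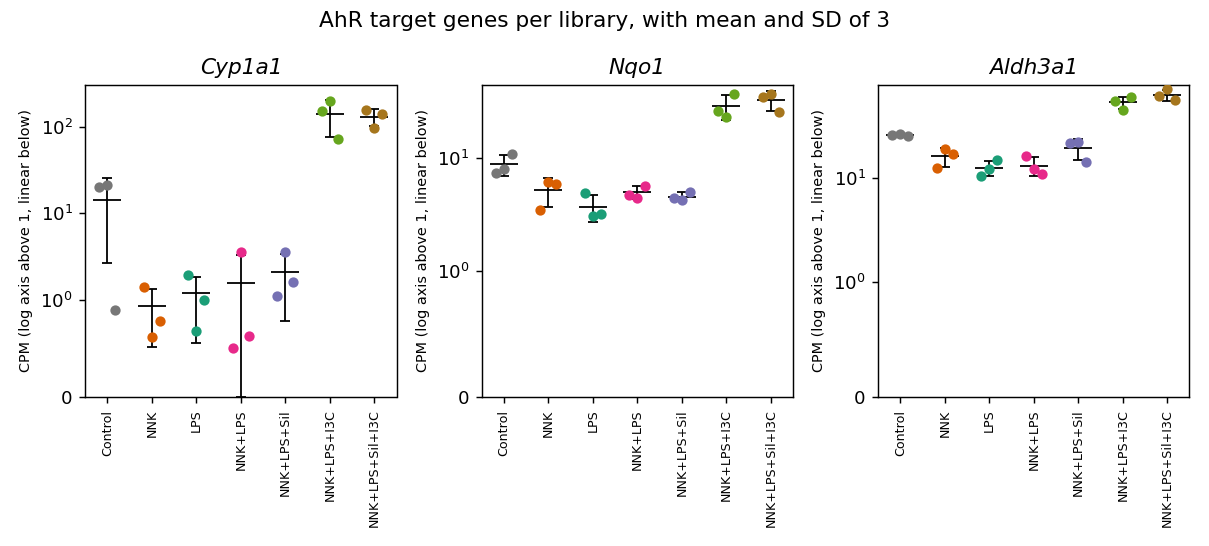
CPM of the AhR target genes Cyp1a1, Nqo1 and Aldh3a1 in the 7 groups, on an axis that is logarithmic above 1 CPM and linear below, with 1 point per library and the mean ± SD of 3 as a bar whose lower end stops at 0. Cyp1a1 averaged 1.58 CPM in NNK_LPS, 2.10 with Sil, 139 with I3C and 130.4 with Sil_I3C.

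Other lists were also called with I3C, 14 in all with those above. With the batch term 3 of the 14 stayed called, AhR targets, NRF2 targets and heart muscle markers, and 2 others were called, the cytokine and the NF-kB and TLR lists. With the 2 groups alone in the fit the same 3 were called. Heart muscle markers rose in 8 of 9 cases, all 9 when adjusted over the list alone (fry adjusted p = 0.00102, adjusted p = 0.173 with an estimated correlation), with the natriuretic peptide gene Nppa at 4.84 ± 0.75. Alveolar type 2 markers fell in 6 of 17 cases, 13 when adjusted over the list alone (fry adjusted p = 0.0130, adjusted p = 0.261 with an estimated correlation), with Napsa at -0.49 ± 0.11. Ciliated cell markers rose in 3 of 12 cases, 11 when adjusted over the list alone (fry adjusted p = 0.0156, adjusted p = 0.261 with an estimated correlation). Xenobiotic-metabolising enzyme genes rose in 3 of 15 cases, with 9 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.0156, adjusted p = 0.269 with an estimated correlation). Summed counts in NNK_LPS and I3C were 150 and 622 for Cyp2e1. The adipocyte genes Adipoq (73 and 635) and Plin1 (65 and 554) moved the same way, and fat tissue in the pieces was not tested. The RAS-MAPK list was called lower with no member called over all genes and 6 of 16 lower when adjusted over the list alone (fry adjusted p = 0.0381, adjusted p = 0.261 with an estimated correlation).

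EdgeR called 318 genes between I3C and NNK_LPS, 193 higher and 125 lower, and 117 changed at least 2-fold. Within batch B, with I3C 1 as the only I3C library, assumed to vary like the libraries of the other groups, 80 genes were called, 25 of them among the 318. Cyp1a1 changed by 6.57 ± 0.96, Nqo1 by 2.37 ± 0.28, Aldh3a1 by 2.06 ± 0.24 and Nppa by 4.23 ± 0.88, while Napsa changed by -0.56 ± 0.18, Gstm1 by 0.70 ± 0.18 and Spag11b by -4.52 ± 1.05, and these 3 were no longer called (adjusted p = 0.152, 0.101 and 0.0916). Nor were other heart muscle genes called, such as Tnni3 (adjusted p = 0.155) and Mybpc3 (adjusted p = 0.0801). The heart muscle covariate, which did not overlap between I3C and NNK_LPS, left 1 called gene and cannot tell heart muscle from group. The batch term gave 60 called genes, DESeq2 1042 and a fit to the 2 groups alone 4. The count was 737 (554 higher and 183 lower) without NNK_LPS 1, 22 without NNK_LPS 2 and 417 without NNK_LPS 3, where the balance turned to 165 higher and 252 lower, and it was 43 and 35 without I3C 1 and I3C 3.

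With both agents in the diet the AhR and NRF2 targets rose again. Cyp1a1 rose by 6.40 ± 0.85, Nqo1 by 2.71 ± 0.24 and Aldh3a1 by 2.26 ± 0.19. Of 7 AhR targets 5 rose by either adjustment (fry adjusted p = 8.63e-09, adjusted p = 0.000280 with an estimated correlation), and of 15 NRF2 targets 8 rose, with 11 higher and 1 lower when adjusted over the list alone (fry adjusted p = 1.89e-06, adjusted p = 0.00515 with an estimated correlation). Clock genes also changed, 2 of 10 higher and 5 lower, with 2 higher and 6 lower when adjusted over the list alone (fry adjusted p = 0.0410, adjusted p = 0.269 with an estimated correlation). Npas2 and Arntl, activators of the clock, rose by 2.91 ± 0.49 and 1.64 ± 0.30, while the clock output gene Dbp changed by -3.31 ± 0.70 and Per3 by -1.95 ± 0.40. Collection times are not given in the labels. Alveolar type 2 markers fell in 3 of 17 cases, 13 when adjusted over the list alone (fry adjusted p = 0.0177, adjusted p = 0.269 with an estimated correlation), with Sftpb at -0.58 ± 0.13. Of the 4 lists called, the AhR and NRF2 targets stayed called with the batch term and with the 2 groups alone in the fit. EdgeR called 214 genes, 87 higher and 127 lower, and 79 changed at least 2-fold. With the batch term 2 were called, Aldh3a1 (2.35 ± 0.33) and Exoc4, which was named after its values were seen, while Nqo1 changed by 2.51 ± 0.41, Cyp1a1 by 6.55 ± 1.29 and Dbp by -4.77 ± 1.31, and these 3 were no longer called (adjusted p = 0.0649, 0.131 and 0.326). The count was 111 (64 higher and 47 lower), 32 (20 and 12) and 775 (293 and 482) without NNK_LPS 1, 2 and 3, and 103, 68 (47 and 21) and 76 without Sil_I3C 1, 2 and 3. It was 672 with DESeq2, 13 (12 and 1) with the 2 groups alone in the fit, 72 with the heart muscle covariate and 1 with the clock covariate. The clock covariate did not overlap between Sil_I3C and NNK_LPS, so its fit cannot tell clock genes from group.

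I3C and Sil_I3C shared 82 called genes against NNK_LPS, 47 higher and 35 lower in both, against 1.06 and 1.01 for independent calls, numbers that leave out the shared NNK_LPS libraries, which raise the overlap by an amount not estimated here. Their fold changes correlated across genes at r = 0.660, within the range of unchanged groups sharing the NNK_LPS libraries, which gave a mean of 0.505 (0.111 to 0.778). The covariance was 0.120, against 0.0415 (0.00717 to 0.0946) with no change. Apart from I3C 1, the I3C and Sil_I3C libraries were of batch C, and those of NNK_LPS were of batch B. The unchanged groups were drawn from deviations from group means, which leave out a batch difference between groups. A shared difference of batch was thus not separated from a shared response to the agents. The mean of the 3 agent groups differed from NNK_LPS in 46 genes, 22 higher and 24 lower, among them Aldh3a1 (1.61 ± 0.17) and Cxcr1 (-1.85 ± 0.33). AhR targets rose in 4 of 7 cases in this mean, 5 when adjusted over the list alone (fry adjusted p = 7.95e-08, adjusted p = 0.000560 with an estimated correlation). The count was 117, 6 and 321 without NNK_LPS 1, 2 and 3, was 26 and 299 without Sil 2 and Sil 3, and was 20 without Sil_I3C 1. The batch term left 1 called gene, Aldh3a1 (1.66 ± 0.22).

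Silibinin and indole-3-carbinol, at 20 µmol/g of diet each, differed in 12 genes, all lower with Sil in this fit, while DESeq2 called 23 higher and 64 lower. Cyp1a1 differed by -6.04 ± 0.82, Nqo1 by -2.65 ± 0.24, Ces1g by -3.37 ± 0.35 and Aldh3a1 by -1.47 ± 0.19. AhR targets were lower in 3 of 7 cases, 6 when adjusted over the list alone (fry adjusted p = 1.34e-07, adjusted p = 0.000238 with an estimated correlation). NRF2 targets were lower in 4 of 15 cases, 10 when adjusted over the list alone (fry adjusted p = 3.28e-05, adjusted p = 0.00628 with an estimated correlation). Within batch B, with I3C 1 again alone and assumed to vary like the other groups, 15 genes were called, and Cyp1a1 differed by -6.12 ± 0.92 and Nqo1 by -2.49 ± 0.28. The count was 21 without Sil 1, 25 without Sil 2 (12 higher and 13 lower), 20 without I3C 1 (3 higher and 17 lower) and 7 without I3C 3, and 0 with the 2 groups alone in the edgeR fit, with 1011 at an unadjusted p under 0.05, against 87 called by DESeq2 on all groups. The effect of both agents together minus the sum of the single effects was called in 0 genes by edgeR, with 1450 at an unadjusted p under 0.05, and in 21 by DESeq2. Without NNK_LPS 1 edgeR called 15 genes in it, and without Sil_I3C 3 it called 2. The number of genes at an unadjusted p under 0.05 in edgeR was 819 without Sil 1 and 2684 without Sil 3.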

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

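The tests in this part were chosen after their results or related values had been seen, except the test of the library batch on the cytokine genes and that of the batch term on the tumour-high genes of Sil_I3C.

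The effect of LPS differed between NNK tumours and lung without NNK, by a test of the difference itself, in 3955 genes. On the log2 scale the difference was 4.68 for Fabp1, 4.52 for Cyp4a12b, 4.32 for Cd209b, 3.52 for Cyp2e1, 3.31 for Grin2b, 3.24 for Bex2, 3.08 for Cd209c and 2.99 for P2rx2. It was -11.64 for Cxcl11, -11.34 for Slc28a1, -10.89 for Irg1, -10.19 for Ubd, -9.90 for Mrgpra2b, -8.98 for Orm2, -8.96 for Gpr84 and -8.55 for Ly6i. Cxcl11 had no counts in Control and 1 in NNK_LPS, Slc28a1 had 3 in NNK_LPS, Mrgpra2b 3 in Control and Cd209b 2 in LPS, so these fitted values rest on few counts and are no bounds. Among list members the difference was -7.01 for Il1b, -5.26 for Lcn2, -2.81 for Oas1a, -4.70 for Csf3r, -2.18 for H2-DMa, 1.84 for Cbr2 and 1.19 for Ephx1. Of 80 splits of the 12 libraries 4 gave as many called genes, the real one included, and the highest other split gave 5823 against 3955. These splits carry the LPS effect of lung into the difference, so they do not show whether chance can be excluded.

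Between NNK_LPS and NNK tumours, mt-Atp8, Rpl23a, H2-T22 and H2-Q1 were higher, and LPS 3 differed from LPS 1 and 2 in these genes by 0.879, 0.621, 0.528 and 0.625 of that log2 change. LPS 3 had a ratio of mt-Atp8 to mt-Atp6 counts of 0.0854, against 0.0206 to 0.0236 in the 8 libraries of batch A. The library batch may thus account for part or all of the change in these 4 genes. Within batch A, LPS 1 and 2 stood above Control in 3 of them. H2-T22 was 12.1 to 17.8 CPM in Control and 51.6 and 48.5 in LPS 1 and 2. H2-Q1 was 8.12 to 10.5, and 27.9 and 24.9. Rpl23a was 140 to 165, and 215 and 198. In contrast, mt-Atp8 was 59.6 to 63.8, and 44.4 and 46.4. For those 3 genes batch and LPS cannot be told apart in the tumours. For the other 11 genes the median share in LPS 3 was -0.0750, from -0.520 for Slc22a3 to 0.499 for Cd63, which is close to the share of H2-T22. That test rests on 1 library of other tissue, so for these 11 genes batch and LPS cannot be told apart. An effect of LPS on the tumours stays open.

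Inflammatory cytokine genes rose with LPS in lung in 24 of 25 cases, and 22 of 25 had a lower LPS effect in tumours. Against the library batch, 20 of the 22 were still called with a batch term, and the median difference was -5.40 without and -5.46 with it. Against a single lower share of inflamed lung in the tumour pieces, the gap between NNK tumours and LPS lung was used. It was taken over genes called higher in LPS lung and over 2-fold above NNK tumours. Of this gap NNK_LPS tumours gained a median of 0.00964 for 24 cytokine genes (quartiles -0.000244 to 0.0249). For 127 immunoglobulin and T-cell receptor segments the median was 0.571 (quartiles 0.283 to 1.16). The tissue, and the time since the last instillation, which the labels do not give, may contribute and were not tested.

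Of the 199 genes at least 2-fold higher in NNK tumours than in Control, the median log2 change against NNK_LPS was -0.62 with Sil_I3C and -0.30 with I3C. With Sil it was -0.076. The 199 genes were also high in LPS lung without NNK. Their mean log2 CPM was 1.33 to 1.59 in the Control libraries, 3.04 to 3.15 in LPS and 2.90 to 3.52 in NNK_LPS. The shares below take Control as normal lung, which had no LPS, while the mice of these tumours received LPS. They therefore cannot weigh an admixture of lung altered by LPS. If normal lung in the pieces were the reason, the falls of 150 of these genes that also differ 2-fold between NNK_LPS and Control would need a median share of 0.594 (quartiles 0.314 to 0.736) in Sil_I3C and 0.369 (quartiles -0.132 to 0.633) in I3C, while the changes of markers lower in NNK_LPS than in Control need other shares: endothelial markers 0.0922 and -0.108, fibroblast markers 0.216 and 0.224, and club cell markers 0.450 and 0.473. These markers disagree, and the endothelial share ran from -0.163 to 0.426 between the Sil_I3C libraries and from -0.511 to 0.256 between the I3C libraries, so more normal lung stays open for both groups. The 113 genes at least 2-fold lower in NNK tumours than in Control rose by medians of 0.51 with Sil_I3C and 1.09 with I3C. For 87 of them the median share was 0.135 in Sil_I3C and 0.558 in I3C. They were not used to weigh this explanation, because heart muscle genes are among them. The library batch stays open: I3C 1, the only I3C library of batch B, gave a median of -0.0555 against -0.36 in I3C 2 and 3, and with the batch term the Sil_I3C median was -0.396. An effect of the agents on the tumours was not separated from these.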

How the results depend on the processing

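All split counts, the thinning, the covariates, the batch settings and the fit without NNK_LPS 2 and Sil 3 were chosen after results were seen. Of 468 named-gene values, all kept direction and side of the threshold with size factors by relative log expression, 467 with DESeq2, 442 without the filter on low counts, 458 after thinning, 456 with the replicate block, 374 with only the compared groups, 350 with the clock covariate, 279 with the batch term and 256 with the heart muscle covariate. The others kept their direction and lost the call, except 1 with DESeq2, which had no adjusted p, and 19 with the heart muscle covariate and 4 with the clock covariate, which reversed. The cause of the changes below was not tested. DESeq2 called 492 genes for NNK_LPS versus NNK, 1042 for I3C, 672 for Sil_I3C, 466 for the mean of the agents, 87 for Sil versus I3C and 21 for the non-additive effect. With only the compared groups in the fit, 4 genes were called for I3C, 13 for Sil_I3C, 4 for the mean of the agents and 0 for Sil versus I3C (1011 at an unadjusted p under 0.05 in edgeR), with fewer samples to estimate the spread. The replicate block gave 37 for NNK_LPS versus NNK and 277 for I3C. The numbers follow the accession order. Residuals of libraries with 1 number correlated at a median of 0.0160 over 63 pairs, 17 of them over 0.1 and 12 under -0.1, and 11 of 21 libraries correlated best with their own number. All 3 pairs were over 0.1 for NNK_LPS with I3C (0.158, 0.276 and 0.262) and for NNK with I3C (0.162, 0.246 and 0.463), so some shared structure is not excluded. Fkbp5 and Zbtb16 also followed the replicate number in most groups, as given below. Camera called 8 lists, and fry with the batch term 75, against 114, of which NNK_LPS versus Control went from 18 to 4 and I3C from 14 to 5.

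The heart muscle covariate gave 78 genes for NNK versus Control, 352 for NNK_LPS versus Control, 6 for NNK_LPS versus NNK, 1 for I3C, 72 for Sil_I3C, 2 for the mean of the agents and 2 for Sil versus I3C. With it the log2 change turned to 0.021 for Tnnc1, 0.071 for Art1, 0.39 for Hrc, 0.18 for Ckm, 0.44 for Mybphl and 0.16 for Acta1 in NNK versus Control. In NNK_LPS versus Control it turned to 0.90 for Xirp2, 0.33 for Ckmt2, 0.81 for Sln, 0.17 for Mybphl, 0.60 for Dhrs7c, 0.13 for Ckm and 2.11 for Acta1. With I3C it turned to -0.36 for Mybphl, -0.17 for Tnnc1, -0.35 for Myl7, -0.13 for Tnni3, -0.12 for Myh6 and -0.50 for Ckm. These are muscle genes, which the covariate itself measures. It did not overlap between Control and NNK, nor between I3C (1.20 to 1.81) and NNK_LPS (-2.17 to -0.42). In such contrasts it removes group differences of any cause, so the lower counts do not show that heart muscle gave the calls. The clock covariate gave 858 for NNK_LPS versus Control, 0 for NNK_LPS versus NNK (1725 at an unadjusted p under 0.05 in edgeR), 2458 for the difference of LPS effects, 1 for Sil_I3C and 1 for the mean of the agents. With it Dbp turned to 0.019, Per3 to 0.24, Arntl to -0.074 and Nr1d2 to 0.22 in Sil_I3C, genes it is built from. The clock covariate did not overlap between Sil_I3C (1.00 to 3.12) and NNK_LPS (-2.94 to -1.55), so the same limit holds. Without NNK_LPS 2 and Sil 3 the counts were 33 for NNK_LPS versus NNK, 40 for I3C, 55 for Sil_I3C and 7 for the mean of the agents. The batch term gave 24 for NNK_LPS versus Control, 0 for NNK_LPS versus NNK, 60 for I3C, 2 for Sil_I3C and 1 for the mean of the agents, and the libraries of 1 batch gave 80 for I3C.

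Leaving out 1 library gave 490 to 1856 genes for NNK versus Control, 6597 to 7242 for LPS versus Control, 2294 to 4380 for NNK_LPS versus Control, 0 to 231 for NNK_LPS versus NNK and 3129 to 3882 for the difference of LPS effects. For Sil it gave 0 in each case, for I3C 22 to 737, for Sil_I3C 32 to 775, for the mean of the agents 6 to 321, for Sil versus I3C 7 to 25 and for the non-additive effect 0 to 15.

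The 10 splits of 6 libraries are too few for a share under 0.05. The real split, 1 of 10, and the highest other gave 2064 and 0 genes for NNK versus Control, 7890 and 0 for LPS versus Control, 3876 and 0 for NNK_LPS versus Control, 15 and 10 for NNK_LPS versus NNK, 318 and 2 for I3C, 214 and 0 for Sil_I3C, and 12 and 2 for Sil versus I3C. For Sil (10 of 10 splits) and the non-additive effect (80 of 80, highest other 656) the real count was 0, which any split reaches, so the comparison says nothing about chance. For Sil the split of NNK_LPS 1, Sil 1 and Sil 2 against the other 3 gave 235 genes, which points to a structure of the samples. For the mean of the agents 6 of 80 splits gave as many genes, with 282 the highest other against 46. That split set NNK_LPS 2, Sil 1 and Sil 3, all without I3C, against the other libraries. Such splits can carry the I3C effect, so they do not show whether chance can be excluded. Thinned to 13.3 M counts, the libraries gave 7606 genes for LPS versus Control, 7451 of them among the 7890, and 275 for I3C, 228 of them among the 318.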

Other observations

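The genes in this part were chosen after their values were seen, and no test was run on them. Fkbp5 and Zbtb16, which glucocorticoids induce, varied between the libraries within groups. Both were lowest in replicate 3 in Control, NNK, NNK_LPS, Sil, I3C and Sil_I3C, though Fkbp5 was near level with Sil_I3C. In LPS both were highest in replicate 3. The differences thus followed the replicate number in most groups and were not scatter within single groups alone. Fkbp5 stood at 114, 89.9 and 14.2 CPM in the 3 NNK libraries and at 116, 99.9 and 16.0 CPM in the 3 NNK_LPS libraries. With Sil it stood at 171, 107 and 20.8 CPM, with I3C at 208, 139 and 25.4 CPM, and with Sil_I3C at 25.1, 25.5 and 24.96 CPM. Zbtb16 stood at 269, 305 and 8.35 CPM in NNK and at 34.4, 24.4 and 13.7 CPM with Sil_I3C.

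Meg3, Rian and Mirg, non-coding RNAs of 1 imprinted locus, moved together between libraries. In NNK_LPS 1, 2 and 3 Meg3 stood at 409, 217 and 74.0 CPM, Rian at 151, 67.4 and 24.4 CPM and Mirg at 9.44, 3.08 and 1.42 CPM. Dlk1, a coding gene of that locus, stood at 2.08, 0.459 and 0.455 CPM in the same libraries and at 23.6, 0.205 and 0 CPM in LPS 1, 2 and 3.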
